A study of Homo sapiens with 6 samples.

How the data were processed

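ACHN cells, an established line from a human renal cell adenocarcinoma, were transfected with a negative control siRNA (group NC) or with 1 of 2 siRNAs against MEX3A (groups siMEX3A_1 and siMEX3A_2), and RNA was taken 48 h later. Each group had 2 libraries, 6 in all. The single-end mRNA libraries were made and sequenced by BGI, per the labels' protocols. STAR and RSEM and the builds GRCh37 and hg19 are named in the submitters' processing notes, with no versions or roles. The strand setting of the counting is not given in the sources used here.

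Each of the 2 deposited tables compares 1 siRNA with NC and has 60409 rows, named by gene symbol, over the same 2 NC libraries. The count columns hold the authors' expected counts per library, not normalized, per the file headers and the values: between 68.6% and 69.4% of the values of a library were whole numbers. The remaining columns are the authors' own comparison, under the column names that DESeq2 writes, per the file headers. Among them the mean normalized count and the test statistic were treated as scores made by the authors. The authors' fold change and its standard error are on the log2 scale, and the remaining columns are the authors' p-value and adjusted p-value per gene. The authors' mean column was rebuilt here from rounded counts and median-of-ratios size factors over 4 libraries to within 4.5e-05.

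Expected counts were rounded to whole numbers before any test. Of the rows, 4481 shared 1369 names and were kept as separate rows without a gene symbol, and 27 carried names that a spreadsheet had turned into dates. Rows that share a name held at most 0.34% of a library. In 23186 rows every library had 0. No row was blank and no column belonged to a library outside the 6. Clone-based names, shared names and date names were not treated as gene symbols when genes were chosen for naming.

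Gene counts were compared with the quasi-likelihood test of edgeR 4.0.16 (R 4.3.3), with TMM scaling, the default filter on low counts and one estimate of spread over all 6 libraries. A gene was called at a Benjamini-Hochberg adjusted p under 0.05, and 18583 genes were tested. The 3 contrasts were siMEX3A_1 minus NC, siMEX3A_2 minus NC and siMEX3A_1 minus siMEX3A_2. Standard errors of log2 fold changes were taken as the fold change divided by the square root of F. In the closing tests, standard errors of medians over genes were taken from the spread over those genes. Such genes are not independent replicates, so these errors do not measure the spread between libraries. Normalized counts are counts divided by the TMM-scaled library size, relative to the mean library. Means are given with the SD of 2 libraries.

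Before the data were examined, 31 gene lists were fixed, covering the cell cycle, stress, metabolism, the extracellular matrix, kidney lineage, RNA regulation and markers of other cell types. The 29 lists with at least 3 tested genes were compared with all other genes by camera (limma 3.58.1) at a preset correlation of 0.01 on log2 CPM with a prior count of 2. Camera p-values were adjusted over the lists. The same test with an estimated correlation rests on the few residual degrees of freedom of 6 libraries, and its adjusted p is given beside each list it affects. The genes named were also set by a rule fixed at that time. It took MEX3A, the tested members of the lists on G1/S regulators, CDK inhibitors and the MEX3 family, up to 4 members of each other list by lowest p in each comparison, and the 10 largest rises and 10 largest falls in each comparison. The last of these needed a gene symbol, an adjusted p under 0.05, a mean of at least 100 normalized counts and both siRNA libraries on the same side of both NC libraries. For genes shared by both siRNAs, the 10 highest and 10 lowest by the smaller of the 2 absolute fold changes were taken under the same minimum. Some genes that this rule names are not reported here.

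Library totals lay between 18825750 and 19158723 counts. The biological coefficient of variation was 6.3%. Pairs of libraries of 1 group differed by more than sampling noise, with a chi-square over its degrees of freedom of 4.32 in NC, 5.62 in siMEX3A_1 and 2.39 in siMEX3A_2, so no library was counted as a repeat of another. The labels do not say whether the libraries of a group came from separate cultures, so the p-values measure only the spread between these libraries, which may be technical. The intervals given for shares of genes are exact 95% binomial intervals.

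The tests were first run on simulated counts with known changes. Of 100 genes changed by 1 on the log2 scale, 79% were recovered for siMEX3A_1 and 84% for siMEX3A_2, with 17787 and 17800 genes tested. At a change of 0.5, 57% were recovered in each comparison. In these runs 4 and 7 unchanged genes were called. Camera called the shifted list and 0 others among 29 simulated for siMEX3A_1 against NC. Genes were simulated independently of each other, so this single run could not show false calls of lists whose members are correlated.

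The alternatives were DESeq2 1.42.0, other scaling, other filters on low counts, fits of 4 libraries, the replicate number as a block, leaving out each library in turn, stricter thresholds, the authors' deposited values, and other set tests. A crossed block and a split of the NC libraries between the siRNAs were added after seeing the data. Unchanged siRNA groups were simulated 50 times against the shared NC libraries to show what these controls alone give.

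For the closing tests, transcript length, GC content and 3′ UTR sequence were taken by gene symbol from GENCODE release files of GRCh38, a build other than the authors'. For this reason no genome coordinates are given. The presence of each 7-mer in 3′ UTRs of at least 50 bases was regressed against fold changes over 11344 coding genes with a mean of at least 50 normalized counts, after UTR length and dinucleotide content. Each of 16326 7-mers found in at least 30 genes received a z-score scaled by the median absolute deviation over all 7-mers and a Bonferroni p. On shuffled fold changes with 1 implanted 7-mer of effect -0.3, the implanted 7-mer ranked first in 10 of 10 runs, and 0 of 10 shuffled sets without it passed. Trends on GC content and length were removed with lowess (statsmodels 0.14.6, Python 3.11.15).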

Results

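The data are RNA sequencing counts of ACHN renal carcinoma cells 48 h after transfection, in 3 groups of 2 libraries. NC received a negative control siRNA, and siMEX3A_1 and siMEX3A_2 each received a different siRNA against MEX3A, which encodes an RNA-binding protein of the KH domain family. The series title places the question in the passage from G1 to S phase and the RB/E2F pathway of clear cell renal cell carcinoma. Library totals were even, from 18825750 counts in siMEX3A_2 replicate 1 to 19158723 in siMEX3A_1 replicate 1. On a multidimensional scaling plot the first axis placed siMEX3A_1 at 1.37 and 1.40 and NC at -1.38 and -1.27. The second axis placed siMEX3A_2 at 1.36 and 1.44, with the remaining libraries between -0.85 and -0.60.

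MEX3A itself was a low transcript in these cells. It had 94 and 109 counts in the NC libraries, 56 and 64 with siMEX3A_1, and 73 and 76 with siMEX3A_2. With siMEX3A_1 its normalized count was 38.9% lower than in NC, a log2 fold change of -0.71 (SE 0.17, 95% interval -1.1 to -0.32, edgeR adjusted p = 0.00655). This call ended with DESeq2 (adjusted p = 0.0593) and is absent from the authors' deposited table (adjusted p = 0.137), and over all alternatives its adjusted p ran from 0.00377 to 0.137. With siMEX3A_2 it was 25.3% lower, a log2 fold change of -0.42 (SE 0.17, 95% interval -0.8 to -0.04) that did not pass the test (edgeR adjusted p = 0.0644). The 2 siRNAs did not differ detectably in their MEX3A level at this depth (log2 difference -0.29, SE 0.18, adjusted p = 0.212). Among the relatives of MEX3A, MEX3D rose with siMEX3A_1 by 0.85 and with siMEX3A_2 by 0.60 on the log2 scale, and MEX3B rose with siMEX3A_2 by 1.11. MEX3B with siMEX3A_1 (0.13) and MEX3C (-0.11 and -0.16) did not pass, and the 4-member family was not called as a list (adjusted p = 0.992 and 0.705).

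The comparison of siMEX3A_1 with NC asks what this siRNA changed in the cell cycle programme and beyond it. Genes of DNA replication and mitosis fell almost without exception. Of the 50 genes of the E2F-regulated DNA replication list, 49 fell and 0 rose, with a median log2 fold change of -1.95 (camera adjusted p = 4.49e-21, and adjusted p = 0.0217 with an estimated correlation). MCM5, a subunit of the replicative helicase, went from 1487 ± 5.68 normalized counts in NC to 118 ± 7.88 (SD, n = 2 libraries each). MCM4 fell by 2.69, thymidine kinase TK1 by 2.43 and DTL by 2.49 on the log2 scale. All 40 genes of the G2/M and mitosis list fell, with a median of -2.15 (camera adjusted p = 1.89e-20, and adjusted p = 0.0217 with an estimated correlation). CDK1, the kinase that drives entry into mitosis, went from 2099 ± 55.2 to 252 ± 1.59 normalized counts, and MAD2L1 and PRC1 fell by 3.11 and 2.90.

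Regulators of the G1 to S passage moved in the same comparison. Of 23 such genes, 15 fell and 3 rose (median -0.79, camera adjusted p = 0.00107). With an estimated correlation the adjusted p of this list was 0.46. Cyclin D1 (CCND1) went from 8218 ± 183 to 2852 ± 143 normalized counts, and its kinase partner CDK6 fell by 1.04 on the log2 scale (SE 0.09). Cyclin E2 (CCNE2) fell by 3.49, the phosphatase CDC25A by 1.54 and the ubiquitin ligase subunit SKP2 by 0.83. The transcription factors E2F1 and E2F2 fell by 2.53 (SE 0.14) and 4.33 (SE 0.29), while E2F7, a repressor of the family, rose by 1.62 (SE 0.11). E2F3 and E2F6 were the other members that rose, by 0.37 and 0.32. The pocket protein genes RBL1 and RBL2 fell by 1.38 and 1.48, and RB1 did not pass (-0.19, SE 0.09, adjusted p = 0.111), though it did without siMEX3A_1 replicate 2 (-0.32, 0.0126) and with library size as the only scaling (-0.26, 0.036). Among CDK inhibitors, CDKN1A (p21) went from 5740 ± 301 to 17350 ± 483 normalized counts and CDKN2B (p15) from 383 ± 0.703 to 1342 ± 109. In that list 2 genes rose, 2 fell (CDKN1C, at -3.18 with SE 0.45 and at -4.57 and -2.48 without siMEX3A_1 replicates 1 and 2, and CDKN3 by 1.34) and 3 did not pass, and the list was not called (adjusted p = 0.555).

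**Figure D1:**
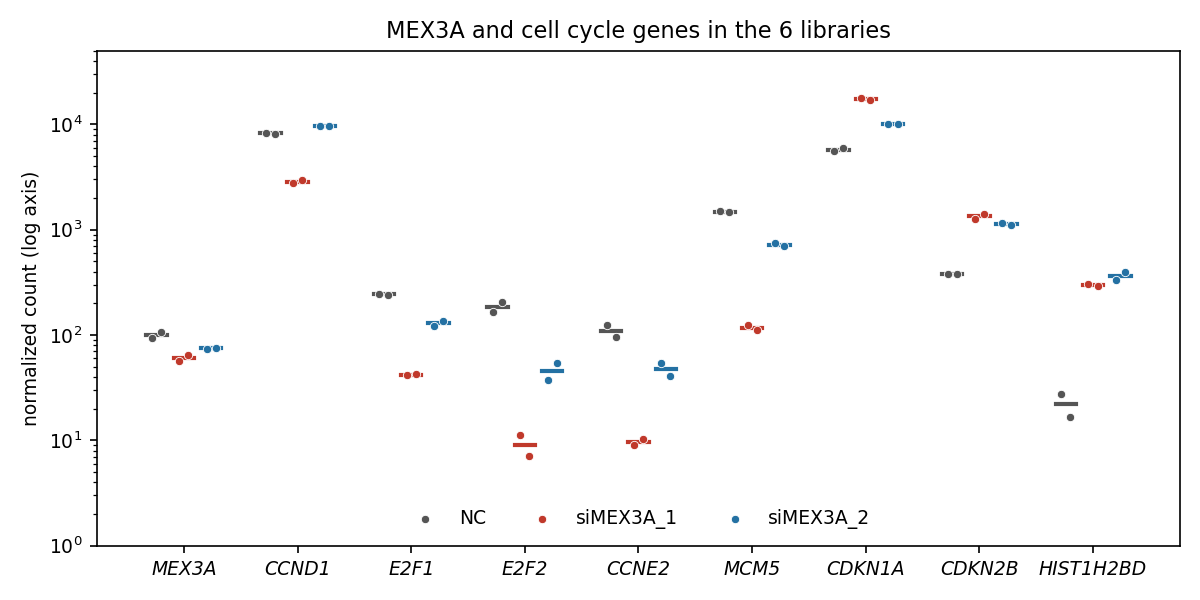
Normalized counts (log axis) of MEX3A and 8 cell cycle or histone genes in the 6 libraries, with points for libraries, horizontal bars for the group means and colours for NC, siMEX3A_1 and siMEX3A_2. CCND1 lies at 8218 in NC, 2852 with siMEX3A_1 and 9585 with siMEX3A_2, while CDKN2B lies at 383, 1342 and 1128.

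Targets of p53 rose with siMEX3A_1: 24 of 25 rose and 0 fell (median 0.89, camera adjusted p = 1.05e-09). The adjusted p was 0.163 with an estimated correlation. Besides CDKN1A, the nuclease gene AEN rose by 1.55, PHLDA3 by 1.33 and BTG2 by 1.41. Replication-dependent histone transcripts rose in 10 of 14 tested members and fell in 0 (median 1.49, camera adjusted p = 0.000789, and adjusted p = 0.192 with an estimated correlation), led by HIST1H2BD at 3.75 and HIST1H4H at 3.36. Lysosome and autophagy genes rose in 22 of 27 and fell in 1 (median 0.56, camera adjusted p = 1.98e-05, and adjusted p = 0.3 with an estimated correlation). Among them was the autophagy receptor gene SQSTM1 (0.68). Endoplasmic reticulum chaperones rose in 14 of 18 and fell in 1 (median 0.56, camera adjusted p = 0.000789, and adjusted p = 0.343 with an estimated correlation). Hypoxia and glycolysis genes rose in 21 of 30 and fell in 4 (median 0.39, camera adjusted p = 0.000789, and adjusted p = 0.3 with an estimated correlation). NDRG1 rose by 2.75, VEGFA by 2.27 and ADM by 2.45. Sterol synthesis and uptake genes fell in 14 of 24 and rose in 3 (median -0.39, camera adjusted p = 0.00235, and adjusted p = 0.192 with an estimated correlation).

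The largest rises with siMEX3A_1 beside these were in the keratin-associated gene KRTAP2-3 (log2 fold change 6.89, SE 0.21, from about 5 normalized counts in NC), the thrombomodulin gene THBD (5.24, SE 0.21) and IGFBP3 (3.99, SE 0.06). NOG, SFN, SIK1 and the long non-coding RNA MIR503HG rose by 3.10 to 3.41. TVP23C-CDRT4 also ranked here, but it is a readthrough of neighbouring genes whose reads the counting could split, and its value is uncertain (3.49, SE 0.62, and 4.32 without NC replicate 1 and 2.88 without siMEX3A_1 replicate 2). The largest falls were in AMBP (-4.62, SE 0.25), SERTAD4 (-4.38, SE 0.08), the mitotic gene DLGAP5 (-4.38, SE 0.11), MCM10, FAM111B, EXO1, SMTNL2, the E-cadherin gene CDH1, ESCO2 and GINS2, the last at -3.81. In all, edgeR called 9836 of 18583 genes, 5014 higher and 4822 lower. Of these, 1304 rose and 1821 fell by at least 2-fold.

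The comparison of siMEX3A_2 with NC repeats the question with a second siRNA. DNA replication genes fell here too, by less: 45 of 50 fell and 1 rose (median -0.64, camera adjusted p = 2.25e-11, and adjusted p = 0.0912 with an estimated correlation). MCM6, a subunit of the replicative helicase, went from 1895 ± 25.5 to 625 ± 16.8 normalized counts. Of 40 G2/M genes, 28 fell and 3 rose (median -0.37, camera adjusted p = 4.69e-05, and adjusted p = 0.141 with an estimated correlation). Cyclin A2 (CCNA2) fell by 2.11 and PLK1 by 1.20. The G1/S list was not called (median -0.05, adjusted p = 0.506), with 11 members lower and 7 higher. Within it E2F1 fell by 0.91 (SE 0.12), E2F2 by 2.03 (SE 0.22), CCNE2 by 1.21, CDC25A by 1.39, SKP2 by 0.79 and cyclin D3 (CCND3) by 1.26. CCND1 rose by 0.22 (SE 0.05, adjusted p = 0.00438), RB1 by 0.67 (SE 0.09) and E2F7 by 1.60, and CDK6 did not pass (0.08, adjusted p = 0.471). CDKN1A rose by 0.82 and CDKN2B by 1.56, and the CDK inhibitor list was not called (adjusted p = 0.506).

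Among other lists with siMEX3A_2, p53 targets rose in 22 of 25 and fell in 0 (median 0.55, camera adjusted p = 1.58e-07, and adjusted p = 0.169 with an estimated correlation), with BTG2 at 1.76 and SESN2 at 1.51. Histone transcripts rose in 12 of 14 (median 1.48, camera adjusted p = 1.61e-05, and adjusted p = 0.141 with an estimated correlation). Lysosome and autophagy genes rose in 18 of 27 and fell in 2 (median 0.40, camera adjusted p = 0.000114, and adjusted p = 0.286 with an estimated correlation), among them the protease gene CTSD (1.26) and MAP1LC3B (1.23). Ribosome biogenesis and MYC target genes fell in 22 of 30 and rose in 2 (median -0.47, camera adjusted p = 5.98e-05, and adjusted p = 0.286 with an estimated correlation). Nucleolin (NCL) fell by 0.92 and spermidine synthase (SRM) by 1.56. Heat shock proteins fell in 10 of 14 and rose in 1 (median -0.54, camera adjusted p = 0.00159, and adjusted p = 0.188 with an estimated correlation), with the chaperonin gene HSPD1 at -1.14. NF-kappaB and inflammatory targets rose in 14 of 22 and fell in 3 (median 0.43, camera adjusted p = 0.0093, and adjusted p = 0.286 with an estimated correlation). TRAF1 rose by 2.48 and CXCL1 by 1.85, while IL6 fell by 1.44. Cytosolic ribosomal protein genes rose in 19 of 53 and fell in 3, with a median of only 0.09 (camera adjusted p = 0.0489). That call ended in 9 alternatives besides an estimated correlation (adjusted p = 0.78 with an estimated correlation), among them without NC replicate 1 (0.211) and without siMEX3A_2 replicate 2 (0.062).

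Sterol synthesis and uptake genes rose with siMEX3A_2 in 14 of 24 and fell in 3 (median 0.31, camera adjusted p = 0.00542, and adjusted p = 0.188 with an estimated correlation), with HMGCS1 at 1.17 and SC5D at 1.21. Endoplasmic reticulum chaperones fell in 9 of 18 and rose in 3 (median -0.39, camera adjusted p = 0.0141, and adjusted p = 0.37 with an estimated correlation). PDIA4, a protein disulfide isomerase, went from 9504 ± 91.5 to 2769 ± 12.1 normalized counts. Hypoxia and glycolysis genes fell in 19 of 30 and rose in 6 (median -0.26, camera adjusted p = 0.0278, and adjusted p = 0.37 with an estimated correlation), with LDHA at -1.05 and CA12 at -1.78, and the glucose transporter gene SLC2A3 among those that rose (1.99). This last call ended without NC replicate 1 (adjusted p = 0.0626), without siMEX3A_2 replicate 1 (0.0525) and with a minimum mean of 50 counts (0.0777).

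The largest rises with siMEX3A_2 were HIST1H2BD (4.04, SE 0.19), HDAC9 (3.23), KLF4 (3.18), CYP1B1 (2.99), EVI2A, the non-coding RNA LUCAT1, EMP1, MAP2, ANKRD1 and SP140. The largest falls were LARGE2 (-5.32, SE 0.26), PIK3R2 (-4.57, SE 0.41, and -3.72 and -6.85 without siMEX3A_2 replicates 1 and 2), the endothelin gene EDN2 (-4.55, SE 0.07), SMTNL2, CDH1, ASIC1, TXNDC5, the zinc transporter gene SLC39A6, MINPP1 and CELSR2, the last at -2.92. In all, 9457 of 18583 genes were called, 4690 higher and 4767 lower, with 1089 rises and 1400 falls of at least 2-fold.

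Changes common to both siRNAs were counted as genes called in the same direction. There were 2610 such rises and 2541 such falls, 5151 genes together, where independent lists of these sizes would share 1265 and 1237. Simulated unchanged siRNA groups against the same NC libraries gave 0 such genes in edgeR. Groups without changes yield few calls at all, so this does not show how far shared controls raise the overlap of long lists. The histone gene HIST1H2BD went from 22.2 ± 7.94 normalized counts in NC to 301 ± 9.60 and 365 ± 45.6. THBD, the transcription factor genes KLF4 and ATF3, the kinase gene SIK1, HIST3H2A, EVI2A, ANKRD1 and KIAA1217 rose by at least 2.31 with siMEX3A_1 and at least 2.35 with siMEX3A_2. CDH1, which encodes the epithelial adhesion protein E-cadherin, went from 739 ± 64.4 to 49.8 ± 17.6 and 60.1 ± 15.6. SMTNL2, SCARF2, CKB, SRRM3, FAM111B, TAGLN3, CELSR2, EDN2 and GALNT6 were the other large shared falls, by at least 2.21 with siMEX3A_1 and at least 2.18 with siMEX3A_2. Across all tested genes, which are not independent replicates, the fold changes of both siRNAs correlated at r = 0.51. Shared controls alone gave a mean of 0.50 in 50 simulations of unchanged groups. Unchanged groups of equal size give about this value whatever the size of the noise. The match therefore does not show how much of r = 0.51 came from shared controls. The covariance, which does depend on the size of the noise, was 0.41 against a simulated 0.0385. With 1 NC library for each siRNA, a split chosen after seeing the data, the covariance was 0.324 and 0.359 in the 2 assignments, and 4003 and 4118 genes were called in the same direction. Part of the excess over independent lists may come from the shared controls.

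**Figure D2:**
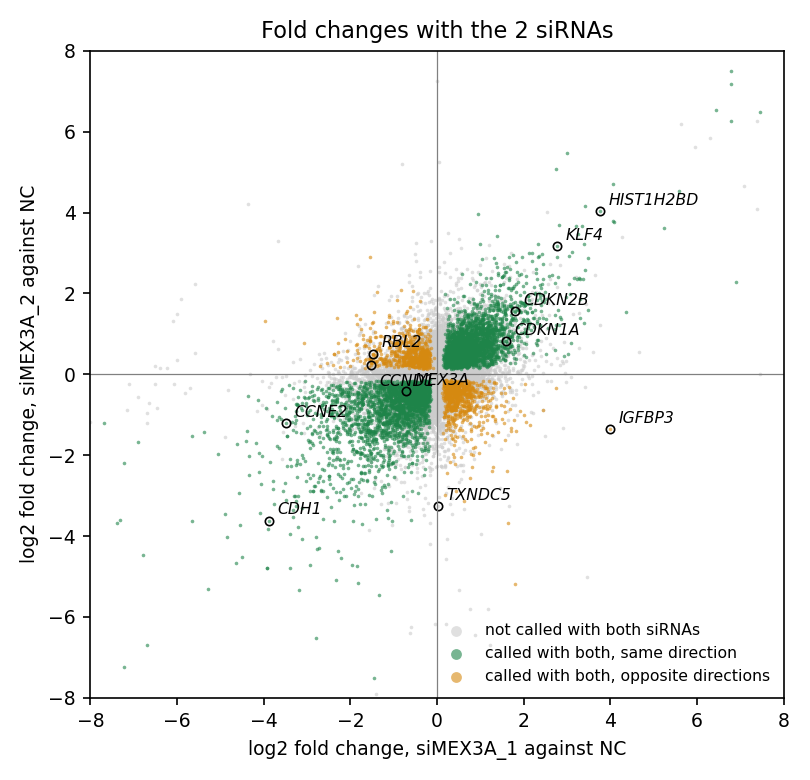
Log2 fold changes against NC of the 18583 tested genes with siMEX3A_1 (horizontal) and siMEX3A_2 (vertical), 1 point per gene, with 9 genes outside the axes. Genes called with both siRNAs in the same direction (5151, green) lie along the rising diagonal, and genes called in opposite directions (1425, orange) fill the other quadrants.

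The direct comparison of siMEX3A_1 with siMEX3A_2 asks where the siRNAs differed. Of the 6576 genes called with both, 1425 moved in opposite directions (21.7%, exact 95% interval 20.7 to 22.7): 754 rose with siMEX3A_1 and fell with siMEX3A_2, and 671 did the reverse. Independent lists of these sizes would hold 1286 and 1217 such genes. Tested directly, 9582 genes differed, 4836 higher and 4746 lower with siMEX3A_1. DNA replication genes were lower with siMEX3A_1 in 44 of 50 and higher in 2 (median difference -1.12, camera adjusted p = 1.18e-13, and adjusted p = 0.0361 with an estimated correlation). Of the G2/M genes, 39 of 40 were lower (median difference -1.69, camera adjusted p = 3.78e-18, and adjusted p = 0.0361 with an estimated correlation). The G1/S list was also lower with siMEX3A_1 (13 of 23 lower, 2 higher, median -0.68, camera adjusted p = 0.0119, and adjusted p = 0.533 with an estimated correlation). CCND1 differed by -1.75 (SE 0.05), RBL2 by -1.99 (SE 0.08) and CDK6 by -1.13. CCNE1, CDC25A, SKP2, E2F3 and E2F7 did not differ detectably, with differences from -0.15 to 0.02.

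The 3 lists called in opposite directions against NC also differed in the direct test. Endoplasmic reticulum chaperones were higher with siMEX3A_1 in 17 of 18 (median difference 1.01, camera adjusted p = 5.63e-08, and adjusted p = 0.219 with an estimated correlation). HSPA5, the main chaperone of this compartment, had 13340 ± 512 normalized counts in NC, 19700 ± 151 with siMEX3A_1 and 9739 ± 179 with siMEX3A_2. Sterol genes were lower with siMEX3A_1 in 22 of 24 (median difference -0.68, camera adjusted p = 6.75e-08, and adjusted p = 0.0757 with an estimated correlation). Hypoxia and glycolysis genes were higher in 23 of 30 and lower in 3 (median difference 0.72, camera adjusted p = 4.15e-06, and adjusted p = 0.219 with an estimated correlation). Ribosome biogenesis and MYC target genes (median difference 0.60, adjusted p = 1.06e-06), heat shock proteins (0.60, 0.0222) and oxidative phosphorylation genes (0.19, 0.0222) were higher with siMEX3A_1. NF-kappaB targets (-0.70, 0.0143) and cytosolic ribosomal proteins (-0.20, 0.0492, and 0.061 with the replicate block) were lower. With an estimated correlation the adjusted p of these 5 lists was 0.246, 0.273, 0.647, 0.31 and 0.838. p53 targets, histones and lysosomal genes were not called in this contrast (camera adjusted p = 0.273, 0.537 and 0.776). Single members still differed, in both directions. With siMEX3A_1, 13 of 25 p53 targets were higher and 7 lower, 3 of 14 histones higher and 3 lower, and 10 of 27 lysosomal genes higher and 9 lower. Single genes with the widest gaps included IGFBP3, at 21260 ± 514 normalized counts with siMEX3A_1 and 523 ± 2.53 with siMEX3A_2, PIK3R2 (log2 difference 4.78, and 3.94 and 7.06 without siMEX3A_2 replicates 1 and 2), GAL3ST1 and TXNDC5 on one side, and EMP1, at 51.8 ± 3.20 and 1133 ± 49.7, RGS9, CCL2 and CKS1B on the other.

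**Figure D3:**
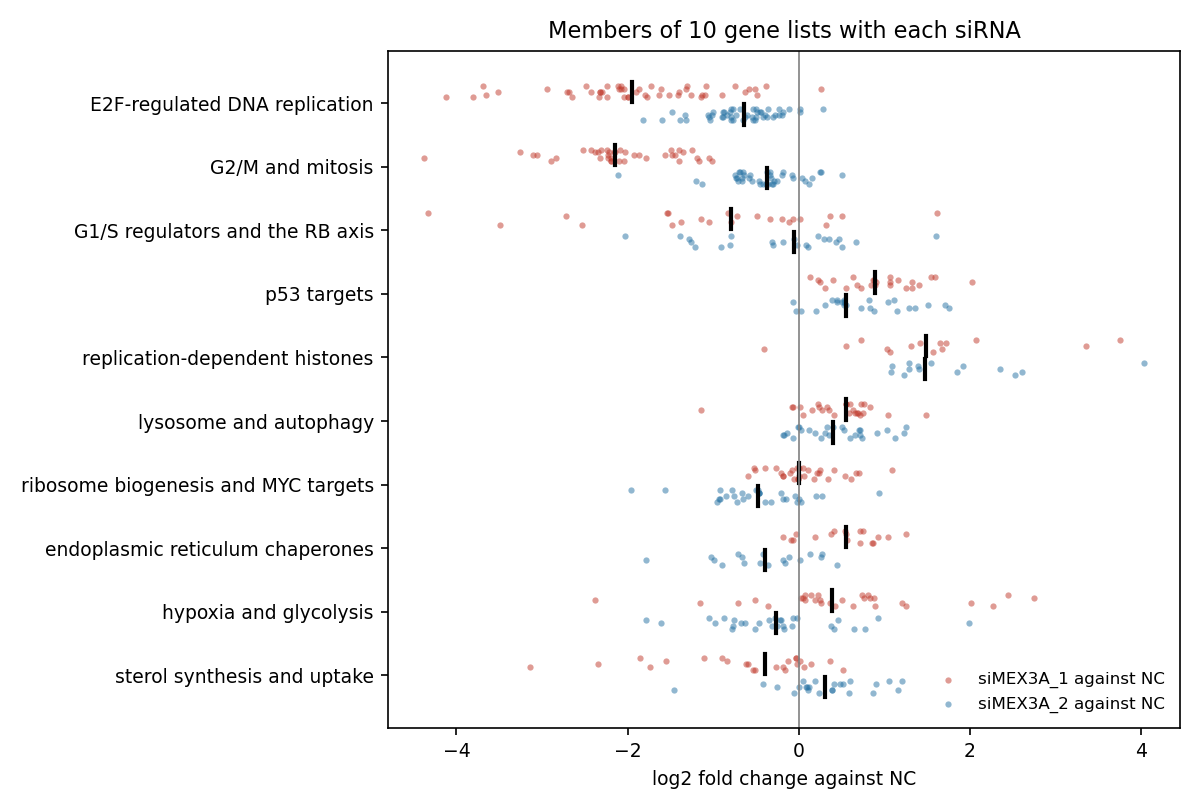
Log2 fold changes against NC of the tested members of 10 gene lists, 1 point per gene, with siMEX3A_1 in red above siMEX3A_2 in blue and black bars at the list medians. The E2F-regulated DNA replication list lies at -1.95 and -0.64 and the sterol list at -0.39 and 0.31.

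The remaining lists were not called against NC with either siRNA, with 1 exception. Fibroblast markers were called lower with siMEX3A_1 (3 of 6 lower, median -0.77, camera adjusted p = 0.0465) and not with siMEX3A_2 (0.101). The member THY1 was lower with both, at 12570 ± 119 normalized counts in NC, 6300 ± 454 with siMEX3A_1 and 5165 ± 46.2 with siMEX3A_2. With siMEX3A_2 the list was called with the replicate block (0.0468) and in the authors' values (0.00712). The list was not called between the siRNAs (adjusted p = 0.634), with 1 member higher and 2 lower with siMEX3A_1. Its call ended without NC replicate 1 (0.0735), without siMEX3A_1 replicate 2 (0.111), with library size as the only scaling (0.0603), with a minimum mean of 50 counts (0.0583) and in a fit of 4 libraries (0.0508), and its adjusted p was 0.614 with an estimated correlation. The adjusted p of the type I interferon response was 0.651 with siMEX3A_1 and 0.14 with siMEX3A_2, that of the integrated stress response and ATF4 targets 0.128 and 0.062, and that of oxidative phosphorylation 0.555 and 0.0569. TGF-beta targets and extracellular matrix gave 0.333 and 0.35, epithelial and mesenchymal markers 0.194 and 0.92, Wnt targets 0.0941 and 0.161, apoptosis regulators 0.519 and 0.111, and renal tubule and kidney lineage 0.196 and 0.0673. Mitochondrially encoded transcripts gave 0.231 and 0.506, nuclear-retained long non-coding RNAs 0.193 and 0.961, housekeeping genes 0.774 and 0.715, the microRNA pathway 0.992 and 0.161, and mRNA decay factors 0.931 and 0.92. Some of these lists passed in other settings. Wnt targets passed with siMEX3A_1 without each library in turn, from 0.0253 without NC replicate 2 to 0.0484 without siMEX3A_2 replicate 1, and without a filter on low counts with both siRNAs (0.0148 and 0.0493). Stress response and ATF4 targets passed without that filter (0.0267 and 0.0143) and in the authors' values (8.91e-05 and 0.000917). With siMEX3A_2, oxidative phosphorylation passed without NC replicate 1 (0.0259), without siMEX3A_2 replicate 2 (0.0389), without the filter (0.0185) and in the authors' values (0.0179). Kidney lineage did so in a fit of 4 libraries (0.0441) and in the authors' values (4.73e-05), apoptosis regulators without the filter (0.0342) and in the authors' values (0.00253), and TGF-beta targets in the authors' values (1.1e-07). With siMEX3A_1, epithelial and mesenchymal markers passed without the filter (0.0227) and in the authors' values (0.00757), and CDK inhibitors in the authors' values (0.039). Heat shock proteins (0.968), cytosolic ribosomal proteins (0.764), ribosome biogenesis (0.519) and NF-kappaB targets (0.555) were not called with siMEX3A_1. Of 10 endothelial and 15 haematopoietic markers, 2 each were tested, 7 and 13 had too few counts, and 1 endothelial marker has no row under its name in the tables. The share of counts from mitochondrial genes was 11.4% and 11.5% in NC, 9.94% and 9.98% with siMEX3A_1, and 11.8% and 11.9% with siMEX3A_2.

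Counts adjusted over the list alone differed from those over all genes by at most 2 genes. With siMEX3A_1, members called higher then numbered 11 and not 10 for histones, 4 and not 3 for the G1/S list, 3 and not 2 for CDK inhibitors, 7 and not 6 for housekeeping genes and 3 and not 4 for the interferon response. Members called lower numbered 25 and not 24 for cytosolic ribosomal proteins, 13 and not 12 for NF-kappaB targets and 9 and not 8 for Wnt targets. With siMEX3A_2, 13 histones and not 12 were higher, as were 8 TGF-beta targets and not 7. Members called lower with siMEX3A_2 numbered 46 and not 45 for the DNA replication list, 29 and not 28 for the G2/M list, 10 and not 9 for endoplasmic reticulum chaperones, 11 and not 10 for heat shock proteins, 6 and not 4 for apoptosis regulators and 1 and not 0 for the MEX3 family, which is MEX3A itself. They numbered 6 and not 5 for epithelial and mesenchymal markers, 7 and not 6 for kidney lineage, 4 and not 3 for nuclear-retained RNAs and 10 and not 9 for mRNA decay factors. Between the siRNAs, members higher with siMEX3A_1 numbered 12 and not 10 for stress response and ATF4 targets and 24 and not 23 for hypoxia and glycolysis. Members lower with siMEX3A_1 than with siMEX3A_2 numbered 8 and not 7 for p53 targets, 6 and not 4 for oxidative phosphorylation, 30 and not 29 for cytosolic ribosomal proteins, 5 and not 4 for kidney lineage and 2 and not 1 for nuclear-retained RNAs. They numbered 10 and not 9 for each of TGF-beta targets, lysosome and autophagy genes and mitochondrially encoded transcripts. All other counts were the same. Median, mean and test differed in sign for CDK inhibitors, the interferon response and mRNA decay factors in both comparisons against NC. They also did so for heat shock proteins, the microRNA pathway and housekeeping genes with siMEX3A_1, and for epithelial and mesenchymal markers and nuclear-retained RNAs with siMEX3A_2, none of which was called in that comparison. Between the siRNAs they differed in sign for CDK inhibitors, the interferon response, lysosome and autophagy genes, kidney lineage and mRNA decay factors, none of them called there.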

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

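In this part the tests of a single effect that differs only in size and of seed matches in the lists' members, the wider set of 6-mers included, were chosen only after the results they bear on, or the seed result given under the other observations, had been seen.

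Each value here was selected because the effects of the 2 siRNAs against the same NC libraries differed in the direct test of siMEX3A_1 against siMEX3A_2. Cyclin D1 (CCND1) was lower with siMEX3A_1 in both libraries (log2 difference -1.75, SE 0.05, adjusted p = 2.02e-08). CDK2, the kinase partner of cyclins E and A, differed by -0.78 (SE 0.065, adjusted p = 7.19e-06), with 2 of 2 libraries lower. RBL2, a pocket protein gene, differed by -1.99 (SE 0.08, adjusted p = 9.53e-08), with 2 of 2 libraries lower.

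Endoplasmic reticulum chaperones (median log2 difference 1.01), sterol synthesis and uptake genes (-0.68) and hypoxia and glycolysis genes (0.72) were called in opposite directions by the 2 siRNAs against NC. None of these calls against NC held with an estimated correlation (camera adjusted p from 0.188 to 0.37), and the hypoxia call with siMEX3A_2 also ended in other settings given above. In the direct test these lists differed with camera adjusted p values of 5.63e-08, 6.75e-08 and 4.15e-06 (adjusted p = 0.219, 0.0757 and 0.219 with an estimated correlation). One effect of MEX3A loss that differs only in size would leave few genes called in opposite directions, and 21.7% of the genes called by both were (exact 95% interval 20.7 to 22.7). Independent lists of the same sizes would give 1286 and 1217 genes in the 2 opposite directions, where 754 and 671 were seen. With library size as the only scaling, applied as 1 constant shift of all fold changes, the medians were 0.96 (SE 0.12), -0.72 (SE 0.19) and 0.68 (SE 0.25). The TMM factors of the siRNA libraries lay between 0.9717 and 1.0077, so this shift could only be small. The choice between these 2 scalings does not account for the differences, and the shift could not judge scaling in general. After removing trends on GC content and transcript length the medians were 0.98 (SE 0.11), -0.75 (SE 0.18) and 0.69 (SE 0.24), so these trends do not account for the differences. These SEs are over list members, not over libraries. Members whose 3′ UTR holds neither 6-mer of the 7-mers GTGTTCA and AGTACAA, inferred from these fold changes as the siRNAs' seed matches, were 10, 9 and 10 genes with medians of 1.08, -1.10 and 0.72 (7, 8 and 10 genes with 1.18, -0.87 and 0.72 when members with any 6-mer of the 2 strongest 7-mers on each side or any 7-mer past the Bonferroni threshold are left out), which argues against matches to these 6-mers in the lists' own members as the whole cause. Effects that pass through other genes silenced by 1 siRNA alone may lie behind the differences and were not tested.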

How the results depend on the processing

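The crossed block and the same-number block in 4 libraries and the split of the NC libraries were added after seeing the data. Apart from that split, where this was not counted, no alternative called any gene in the direction opposite to the edgeR call. Of 6680 values of the 278 named genes under alternatives, 6621 kept their direction or stayed uncalled on the same side of the threshold, 50 lost a call, 9 gained 1 and 0 reversed, and 37 of the 6621 changed sign while uncalled in either setting. With a minimum absolute log2 fold change of 1, the called genes numbered 3125 for siMEX3A_1 against NC, 2489 for siMEX3A_2 against NC, 2764 between the siRNAs and 1040 in the same direction with both, by the construction of that threshold. The authors' deposited values gave 3406 genes called in the same direction by both siRNAs, and the cause was not tested. MEX3A with siMEX3A_1 was at -0.71 with DESeq2 (adjusted p = 0.0593) and -0.71 in the authors' values (adjusted p = 0.137). With siMEX3A_2 it was at -0.43 with a minimum mean of 50 counts, where fewer genes were tested (adjusted p = 0.0487), against a range of 0.0572 to 0.392 over the other alternatives. With an estimated correlation, camera called 2 lists for siMEX3A_1 and 0 for siMEX3A_2, against 10 and 12 at the preset correlation. Fry, which tests each list on its own and not against other genes, called 23 and 23. Leaving out 1 library at a time moved the correlation of both siRNAs between 0.457 (without siMEX3A_1 replicate 2) and 0.61 (without NC replicate 1). With its own NC library for each siRNA it was 0.323 and 0.372 in the 2 assignments, where no control is shared and each has 1 library. In the same runs the called genes ranged from 8393 to 9326 for siMEX3A_1, from 7274 to 9796 for siMEX3A_2 and from 7557 to 9380 between the siRNAs, with the lone library of a group assumed to vary like the others. With the replicate number as a block the counts were 9328, 8932 and 9101. The deviations of equal numbers correlated at -0.33 between NC and siMEX3A_1. They correlated at 0.12 between NC and siMEX3A_2 and at -0.05 between the siRNAs, so equal numbers do not pair the libraries throughout. The -0.33 means that unequal numbers of NC and siMEX3A_1 tended to deviate together, and its cause was not tested. In the 4 libraries of siMEX3A_1 and NC, the same-number block called 8243 genes and the crossed block 10571. With library size as the only scaling, 45.8% of the genes called for siMEX3A_1 were higher, against 51.0% with TMM, and the median over all genes was -0.07 against -0.01. A pseudocount alternative does not apply to counts, and the authors' tables hold no comparison between the siRNAs. At this depth MEX3A itself had 56 to 109 counts per library, which limits the precision of its fold change. Of the 26 histone genes, 11 had too few counts for a test, at most 13 in any library (HIST1H1E), and HIST1H4C reached 5. As 1 more shares its name between rows, the histone results cover only 14 members. Whether depth or the making of mRNA libraries left the 11 so low was not tested.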

Other observations

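In this part the tests of library size and of seed matches as the whole cause were chosen only after the result was seen, and the tests of seed matches in DNA replication genes and of a wider set of 6-mers and 7-mers after the seed result was seen.

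Genes of kidney lineage, called as a list with neither siRNA in the edgeR comparisons of 6 libraries, moved one by one. PAX2, a transcription factor of the developing kidney, had 2585 ± 126 normalized counts in NC, 1729 ± 102 with siMEX3A_1 and 652 ± 48.3 with siMEX3A_2 (adjusted p = 0.000114 and 1.47e-07 against NC). The kidney cadherin gene CDH16 fell from 280.5 ± 2.17 to 47.7 ± 1.14 and 99.6 ± 12.1 (adjusted p = 4.75e-07 and 1.11e-05). LHX1 rose with siMEX3A_1 from 248.5 ± 5.24 to 838.6 ± 33.3 (adjusted p = 9.35e-08), and the peptidase gene MME rose with siMEX3A_2 from 149.6 ± 7.47 to 378.8 ± 1.00 (adjusted p = 4.93e-06). In all, 1 of 13 tested members rose and 6 fell with siMEX3A_1, and 3 rose and 6 fell with siMEX3A_2 (7 adjusted over the list alone).

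Single genes of adhesion, cytoskeleton and matrix also changed in lists that were not called. The intermediate filament gene VIM rose by 1.16 with siMEX3A_1 and by 0.43 with siMEX3A_2 on the log2 scale (adjusted p = 1.55e-08 and 7.32e-06), and SNAI2, a repressor of CDH1, rose by 2.78 and 1.58 (adjusted p = 1.52e-07 and 1.43e-05). The keratin genes KRT8 and KRT19 rose with siMEX3A_1 by 1.23 and 1.36 (adjusted p = 3.70e-08 and 6.00e-08). THBS1 and LOXL2 fell with siMEX3A_2 by 2.09 and 1.91 (adjusted p = 5.89e-08 and 2.49e-08). SPARC fell with siMEX3A_1 by 2.21 (adjusted p = 4.98e-09) and was at -0.48 with siMEX3A_2. FN1, of the same list, rose by 1.72 with siMEX3A_1 (edgeR adjusted p = 2.63e-08) and was at 1.36 with siMEX3A_2. Of the 26 tested TGF-beta and matrix genes, 7 rose and 12 fell with siMEX3A_1, and 7 rose and 10 fell with siMEX3A_2. Of apoptosis regulators, BCL2L1 rose by 0.80 and 1.01, and BIRC3 fell with siMEX3A_1 by 2.27.

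With 9836 and 9457 genes called for the 2 siRNAs, and MEX3A 38.9% lower (a call that ended with DESeq2) and 25.3% lower (not past the threshold), the library totals, with the largest 1.02 times the smallest, leave no room for depth as the cause. A candidate explanation is silencing of other transcripts through the siRNA seed: in a regression over 11344 genes and 16326 7-mers of 3′ UTRs, the 1664 carriers of GTGTTCA were lower on average with siMEX3A_1 than with siMEX3A_2 (robust z -19.68, the lowest of the 7-mers), with a log2 effect against NC of -0.43 with siMEX3A_1 and -0.01 with siMEX3A_2. On the other side the 1107 carriers of AGTACAA were lower on average with siMEX3A_2 (robust z 10.03, the highest of the 7-mers). Their effects were -0.26 with siMEX3A_2 and 0.00 with siMEX3A_1. GAGTACA was nearly tied (robust z 9.98, effect -0.30 with siMEX3A_2). Of the cell cycle genes named above as lower with siMEX3A_1, MCM5, MAD2L1, PRC1, CCNE2, E2F2 and CDK6 carry GTGTTCA. MCM4, TK1, DTL, CDK1, CCND1, CDC25A, SKP2, E2F1, RBL1, RBL2, CDKN1C and CDKN3 do not. Named genes do not stand for their lists. GTGTTCA was carried by 4 of 50 DNA replication genes, 5 of 40 G2/M genes, 5 of 23 G1/S regulators and 0 of 7 CDK inhibitors. Of all 13387 tested coding genes with a 3′ UTR, 1891 carried it. Among the 10 largest falls, SERTAD4, DLGAP5, MCM10, CDH1, ESCO2 and GINS2 carry it, and AMBP, FAM111B, EXO1 and SMTNL2 do not. It was carried by 24.8% of genes at least 2-fold lower with siMEX3A_1 and 12.5% of uncalled genes, on the fold changes that picked it. Matches in the changed genes themselves are not the whole cause. Of the 5148 genes with neither 6-mer of GTGTTCA and AGTACAA, 60.0% or more were called with each siRNA. The 22 DNA replication genes without one had medians of -2.02 (SE over genes 0.23) and -0.52 (SE over genes 0.09). Without any 6-mer of the 2 strongest 7-mers on each side or any 7-mer past the Bonferroni threshold, 60.3% or more of 4446 genes were called. The 19 DNA replication genes left then had medians of -1.80 (SE over genes 0.27) and -0.53 (SE over genes 0.07). Only 4 of the 23 G1/S regulators held neither 6-mer, too few to judge that list in this way. Open are indirect effects of genes silenced by seed matches and effects of MEX3A loss. Differences between cultures apart from the siRNAs are open too, since the labels do not say whether libraries of a group came from separate cultures. The siRNA sequences are not given in the sources used here, and both 7-mers occur in the MEX3A transcript, as 27.0% of all 7-mers do.

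Replication-dependent histone transcripts, which carry no poly(A) tail in cycling cells, were called higher with both siRNAs, in 10 and 12 of 14 tested members (adjusted p = 0.192 and 0.141 with an estimated correlation), while DNA replication genes were called lower (adjusted p = 0.0217 and 0.0912 with an estimated correlation). Trends on GC content and length do not account for this, since the histone medians after their removal were 1.47 (SE 0.35) and 1.51 (SE 0.27). More RNA without a poly(A) tail in the siRNA libraries cannot be told apart from a change in the histones, because only 4 other such RNAs had enough counts, with medians of 0.18 (SE 0.71) and 0.02 (SE 0.73). Among these, named after their values were seen, SNORD3A rose with siMEX3A_1 and RN7SL2 fell with siMEX3A_2. A switch of histone genes to polyadenylated transcripts in cells that leave the cycle may also lie behind the rise and was not tested, since counts per gene do not show transcript ends.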
